A study of Homo sapiens with 8 samples.

How the data were processed

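RNA from 8 SKOV3 cultures was sequenced with a directional library kit, per the labels, which describe the 2 libraries of each line as untreated cells from distinct culture passages and RNA of a stated minimum integrity. The authors deposited raw counts per gene in 1 table for the whole series, which the file's own description and its summary lines attribute to HTSeq. The submitters' processing notes name bcl2fastq 2.18.0.12, STAR 2.7.3a, HTSeq 0.11.3, DESeq2 1.26.0 and the build GRCh38 without their roles. The annotation release, the strand setting of the counting and any filter are not given in the sources used here. Where the counting did not use strand, reads of a gene and an overlapping gene on the other strand cannot be told apart, so overlapping and antisense genes are uncertain. Genes with near-identical copies lose reads that map to several places, and counts of families such as keratins, SPANX, histones and HLA genes are uncertain for that reason.

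The table held 67008 genes and 5 summary lines that name no gene, which stayed out of library sizes and tests. As a share of all counted reads, those without an annotated feature made up 1.48% to 10.0%, those that fit several genes 9.51% to 12.8% and those that mapped to several places 10.3% to 25.1%. All 8 columns matched a sample by its title, and unmatched columns numbered 0. Biotypes and GRCh38 coordinates came from GENCODE 29. Gene symbols came from a separate gene name reference, or from GENCODE 29 where that had none. Together they named 60649 identifiers (90.5%). Protein-coding genes held 97.9% to 98.5% of gene counts and mitochondrial genes 2.56% to 4.35%. Libraries of 1 line had rank correlations of 0.925 (KO 2F4) to 0.972 (KO 5H5). Their counts differed by more than sampling noise in every line (chi-square per degree of freedom 91.9 to 191). Neither is therefore a second sequencing of the other alone. Libraries of a line were not always the closest pair. Parental 2 correlated at 0.943 with KO 5H5 1 but at 0.934 with parental 1. KO 2F4 1 correlated at 0.942 with KO 5H5 1 but at 0.925 with KO 2F4 2. Each library was counted as a replicate because the labels call it one.

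Libraries were numbered within a line by their title, replicate 2 being the one with the suffix UnTx. What the suffix means is not given in the sources used here, since the labels call all 8 libraries untreated, so the 2 libraries of a line may differ in more than passage. Counts were scaled with TMM (factors 0.779 to 1.21) and filtered with filterByExpr (minimum count 10, minimum total 15). Tests were edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Knockout against control used all 8 libraries as 2 classes. A second test used counts summed per line, 2 lines per class. The 6 comparisons of lines used 1 mean per line and a spread shared by all lines. Fold changes are on the log2 scale with standard errors from the fitted model, and log2 CPM used a prior count of 2. P-values of the 8 libraries as 2 classes rest on the spread within a class, which mixes differences between its 2 lines and between passages. They take the 2 libraries of a line as independent. P-values of the line comparisons measure the spread between culture passages, not between independently made clones.

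The design, the tests, most alternatives, the 32 gene lists and the rule for named genes were fixed before the data were examined. The rule took PDE10A, the 12 largest rises and the 12 largest falls among called protein-coding genes with a mean of at least 1 CPM and no overlap between classes, up to 4 genes with the smallest p of each list, 7 genes always, and the 5 largest rises and 5 largest falls of EV 1B9 against parental and of KO 2F4 against KO 5H5. Genes outside the rule are said to be so where they are named. The lists held 1071 symbols, of which 1069 matched the table, and 30 lists had at least 3 tested members. Lists were tested with camera from limma on log2 CPM with a preset correlation of 0.01, beside an estimated correlation and fry, which asks whether a list moves 1 way on balance without comparing it with other genes.

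Alternatives were RLE size factors, no filter, DESeq2, the title suffix as a block, leaving out each library, 1 mean per line, limma-voom with the line as a random block, either control alone, either clone alone and a size threshold. Offsets for GC content and gene length (natural splines with 5 degrees of freedom per library), alone and with the block, the omission of parental 1 with KO 2F4 2, and the list tests with 1 control or 1 clone alone were added after the data were seen. When a library was left out of a line, the remaining one was assumed to vary like those of the other lines. Overlaps between clones were set beside the product of list sizes and beside 20 simulations of unchanged lines. Shifts of neighbouring genes were counted in windows of 50 genes with 100 shuffles of gene order.

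The spread within a class or line and the 2 libraries per line set the precision of the tests, and the counts per library set the floor. A gene with no count in a library could lie at up to 0.0864 CPM (EV 1B9 1) to 0.229 CPM (parental 1), taking 3 counts as the floor, and folds against a group without counts use 3 counts over that group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The tests were run on simulated counts with 200 genes changed. For knockout against control over 13508 genes, 0% of 2-fold changes, 29.9% of 4-fold and 75.8% of 8-fold changes were recovered, with 3 false calls, and with lines as the unit over 16052 genes 0%, 2.99% and 40.9%, with 2 false calls. For EV 1B9 against parental over 15551 genes the shares were 1.49%, 44.8% and 59.1%, and for KO 2F4 against KO 5H5 1.49%, 26.9% and 68.2%. A simulated 2-fold fall of the 22 beta-catenin targets was called by camera in 10 of 10 draws and in 8 with an estimated correlation. Another list was called in 3 draws. Beyond the set changes, simulated libraries of a line shared no difference and genes were uncorrelated. In the data, limma-voom estimated a correlation of 0.341 within a line. The simulated false calls and list calls therefore do not give error rates where lines differ or genes move together. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.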

Results

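RNA was sequenced from SKOV3, an established human ovarian cancer cell line, in the parental culture, in the clone EV 1B9 that carries an empty vector, and in the knockout clones KO 5H5 and KO 2F4, in which PDE10A was targeted. PDE10A is a phosphodiesterase that degrades cAMP and cGMP. Each of the 4 lines had 2 libraries, labelled as biological replicates from distinct culture passages, which gave 4 libraries without the knockout and 4 with it. Counts assigned to genes summed to between 15483683 (parental 1) and 28648044 (EV 1B9 1) per library. Reads outside annotated genes or with no unique gene made up 24.1% (KO 5H5 2) to 44.6% (parental 1) of all counted reads, and KO 2F4 2 had 33.4%. The rank correlation of expression with GC content also differed between libraries, from -0.494 in EV 1B9 2 to 0.413 in KO 2F4 2, so gene counts with offsets for GC content and length stand beside the uncorrected ones where they differ. Levels are TMM-scaled CPM, counts relative to library size, given as mean ± SD.

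PDE10A (ENSG00000112541.15, chromosome 6, 165327287 to 165988078 on GRCh38) was read first, since its level bears on the labels. The control libraries held 120 and 55 counts in parental and 183 and 220 in EV 1B9. The knockout libraries held 4 and 12 counts in KO 5H5 and 4 and 31 in KO 2F4, so all 4 lay below all 4 controls. The mean was 6.34 ± 3.16 CPM in the controls and 0.779 ± 0.989 CPM in the knockout libraries (SD, n = 4 each). The log2 fold change was -3.07 (SE 0.84), with an adjusted p of 0.0988 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and without KO 2F4 2 it was -4.48 with an adjusted p of 0.0135. Against EV 1B9 alone, PDE10A fell by 4.32 on the log2 scale in KO 5H5 (SE 1.08, adjusted p 0.0351), while KO 2F4 gave -2.52 (SE 0.98, adjusted p 0.101). Counts cover the whole annotated gene and do not show where the edit lies, which is not given in the sources used here.

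**Figure D1:**
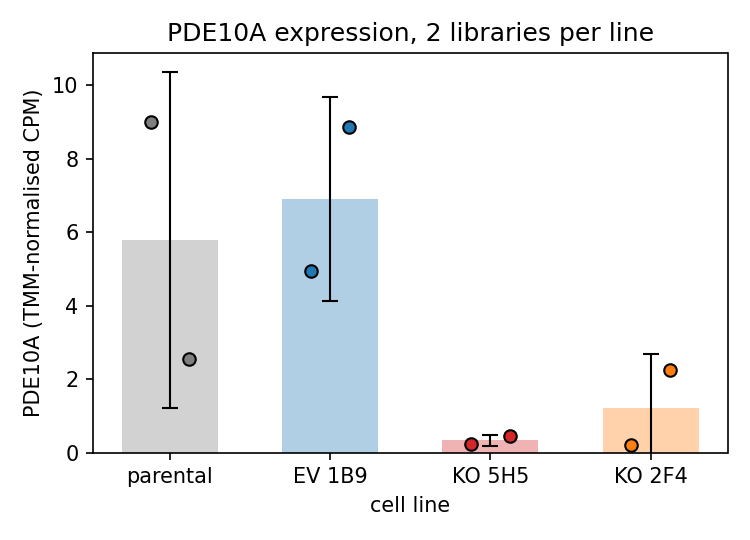
TMM-normalised CPM of PDE10A on the vertical axis in the 4 lines, where bars are means of 2 libraries, points are libraries and error bars are SDs (the lower bar is truncated at 0 in KO 2F4). Means were 5.77 CPM in parental, 6.90 in EV 1B9, 0.333 in KO 5H5 and 1.23 in KO 2F4.

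The central comparison set the 4 knockout libraries against the 4 libraries of the parental line and the empty vector clone, asking which genes differ with loss of PDE10A. Some keratins of basal epithelial cells were among the deep falls. KRT14 (ENSG00000186847.6, chromosome 17, 41582279 to 41586921) went from 1154 ± 1112 CPM to 0.153 ± 0.245 CPM (n = 4 each), a fall by 12.97 on the log2 scale (SE 1.40, adjusted p 0.000695 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). KRT5 (ENSG00000186081.12, chromosome 12, 52514575 to 52520687), its usual dimer partner, fell by 9.88 (SE 1.44, adjusted p 0.00524), from 2476 ± 2502 CPM in controls to 5.28 CPM in KO 5H5 and 0.123 CPM in KO 2F4, and KRT6A fell by 6.71 (SE 0.98, adjusted p 0.00524), from 13.4 ± 13.9 to 0.125 ± 0.152 CPM. For KRT14 the wide SD of the controls reflects the 2 lines, with 219 ± 128 CPM in parental and 2088 ± 448 CPM in EV 1B9 (n = 2 each), while KRT5 also varied within EV 1B9 (4223 ± 2520 CPM). KRT15, another basal keratin and outside the naming rule, did not pass (log2 fold change -0.28, SE 0.73, adjusted p 0.883, edgeR). It had 3.44 CPM in controls and 2.94 CPM in knockout libraries. Keratin genes have close paralogs, and their counts are uncertain to the extent that shared reads were left out or divided.

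Other deep falls were in genes of varied function. DPYSL5 (ENSG00000157851.17, chromosome 2, 26847747 to 26950351), a collapsin response mediator, fell by 9.26 on the log2 scale (SE 0.87, adjusted p 0.000435, edgeR), from 95.8 ± 32.7 to 0.161 ± 0.276 CPM (n = 4 each). NMUR2, a neuromedin U receptor, fell by 8.64 (SE 0.89, adjusted p 0.00054), from 26.8 to 0.0663 CPM. MGAT3, the transferase that adds bisecting N-acetylglucosamine to N-glycans, fell by 8.31 (SE 0.86, adjusted p 0.00054), from 40.9 ± 15.5 to 0.127 ± 0.185 CPM. The synaptic adhesion gene NLGN4X had no count in any knockout library and was at least 160-fold lower, with the floor set at 3 counts over the group, and CBFA2T3, a transcriptional corepressor, and UBE2QL1 were at least 80.3-fold and 63.2-fold lower on the same floor. TAFA5, a secreted protein, had 1 count in the knockout libraries, a ratio of control to knockout of 185 with a 95% counting interval of 32.8 to 7324. RAI2 and AMTN completed the 12 deepest falls, with log2 fold changes of -6.86 (SE 0.96, adjusted p 0.00415) and -6.72 (SE 1.23, adjusted p 0.0187).

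Fewer genes rose. MLLT11 (ENSG00000213190.3, chromosome 1, 151057758 to 151068497), known as a fusion partner of MLL in leukaemia, rose from 3.05 ± 0.908 to 60.5 ± 16.3 CPM (n = 4 each), a log2 fold change of 4.27 (SE 0.39, adjusted p 0.000435, edgeR). The small heat shock protein gene HSPB8 rose by 4.56 (SE 0.73, adjusted p 0.00865), from 0.985 ± 0.917 to 23.2 ± 5.45 CPM. SPANXB1, a cancer-testis gene with near-identical copies on chromosome X whose reads may be divided among them, rose by 5.52 (SE 0.94, adjusted p 0.0138), from 2.38 ± 2.42 to 108 ± 94.3 CPM. COPZ2, a coatomer subunit, rose by 4.12 (SE 0.78, adjusted p 0.0208), and AP1M2, an adaptor subunit of epithelial sorting, rose too (adjusted p 0.0173), from 15.7 ± 12.7 to 129 ± 53.1 CPM. The other 7 of the 12 largest rises were PLXNB3 (5.38), MFAP2 (4.80), PHYHIP (4.64), ARSI (4.49), MYO15B (3.63), B4GALNT1 (3.41) and CDC42EP1 (3.10), which include a semaphorin receptor, a microfibril glycoprotein and a ganglioside synthase, with adjusted p between 0.0138 and 0.0461.

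**Figure D2:**
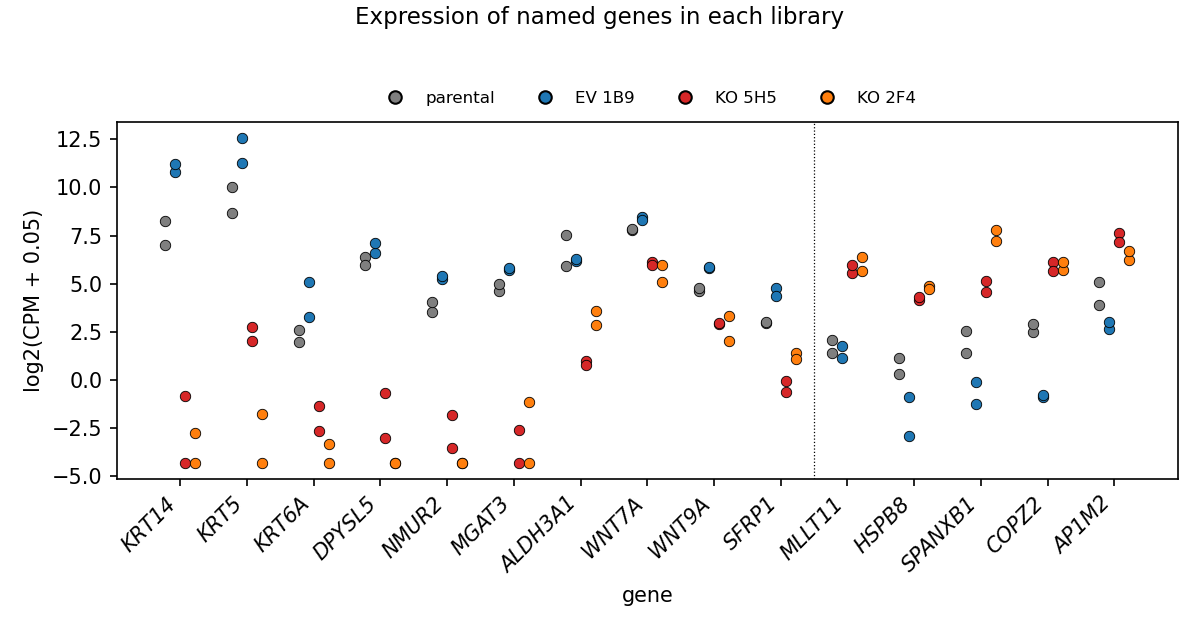
Level of 15 named genes in each library as log2(CPM + 0.05) on the vertical axis, with genes on the horizontal axis, 1 point per library and colours for the 4 lines. KRT14 to SFRP1, left of the dotted line, fell in the knockout libraries and MLLT11 to AP1M2 rose, and the points of the knockout libraries lie on 1 side of all control points for each gene.

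Of 13508 genes tested, 192 passed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 40 higher and 152 lower (79.2%), and 170 of the 192 are protein coding. The excess of falls depends on the control and the model. There were 515 higher and 397 lower genes against EV 1B9 alone, 4 and 43 against parental alone, and 515 and 593 with 1 mean per line. All 192 had no overlap between the 4 knockout and 4 control libraries, against 1391 genes (10.3%) without overlap among all tested. Chance gives 2.86% if all libraries are independent, and more for genes that differ by line. The excess over 2.86% therefore cannot be tied to the knockout. In the 4 comparisons of a single clone with a single control, 54 genes were called in all (9 higher, 45 lower), among them KRT14 and MLLT11. With offsets for GC content and length, 550 genes passed, 244 higher and 306 lower, including 190 of the 192 in the same direction, while the median log2 fold change of all genes moved from -0.14 to 0.04. The count depended on single libraries and was 69 without EV 1B9 1, 79 without EV 1B9 2, 65 without KO 5H5 1 and 77 without KO 2F4 1. Limma-voom with the line as random block, which takes libraries of a line as related, called 34. The edgeR p-values rest on the spread within a class, which mixes differences between lines and between passages. They take the 2 libraries of a line as independent, and 2 lines per side is the number that bears on a knockout effect.

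With counts summed per line, so that the line was the replicate, 11 of 16052 genes passed and all 11 were among the 192. MGAT3 (log2 fold change -8.24, SE 0.91, adjusted p 0.0370 by edgeR's quasi-likelihood test), KRT14 (-12.96, SE 1.45, adjusted p 0.0370), DPYSL5 (-9.29, SE 1.09, adjusted p 0.0383) and NMUR2 (-8.71, SE 1.14, adjusted p 0.0383) were lower. GALNT16, a mucin-type glycosylation enzyme, MATK, a Src-inhibiting kinase, COX7A1, a respiratory chain subunit, CACNA1H, a T-type calcium channel, PI16 and ENSG00000259017.1, 6 genes outside the naming rule, also fell, with log2 fold changes between -12.40 and -4.52. MLLT11 alone was higher, by 4.30 (SE 0.54, adjusted p 0.0383). With GC and length offsets 0 genes passed in edgeR, with 1471 at an unadjusted p under 0.05 and 263 called by DESeq2 without the offsets, although all 11 kept their direction (KRT14 -13.45, SE 1.86, and MLLT11 4.26, SE 0.41) at adjusted p between 0.143 and 0.197.

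Target genes of beta-catenin and TCF, a pathway the study's title names, were lower on balance in the knockout libraries, with exceptions. The list of 22 tested members had a median log2 fold change of -0.72 and passed camera with a preset correlation (adjusted p 0.0211 over 30 lists) and fry (adjusted p 0.0162), but had an adjusted p of 0.398 with an estimated correlation, at which no list passed. In edgeR 0 members were called over all genes tested, with 12 at an unadjusted p under 0.05, and adjusted over the list alone 7 fell. These were NOTUM, which inactivates Wnt ligands (-3.19, SE 0.96), MMP7, a matrix protease (-3.92, SE 1.18), ID2 (-2.22, SE 0.67), SOX4 (-1.44, SE 0.44) and, named after their values were seen, EPHB3, TNFRSF19 and FGF18, with p adjusted over the list alone between 0.0344 and 0.0495. CTNNB1, which encodes beta-catenin, was 51.2 ± 28.3 CPM in controls and 67.2 ± 12.5 CPM in knockout libraries (log2 fold change 0.33, SE 0.42, adjusted p 0.743). The Wnt targets MYC (0.45, SE 0.34, adjusted p 0.56), BIRC5 (0.01, SE 0.36, adjusted p 0.995) and CCND1 (-0.39, SE 0.34, adjusted p 0.615) did not pass. The camera call was lost without parental 1 (adjusted p 0.0682) and with EV 1B9 alone as control (adjusted p 0.167), the latter tested after the data were seen. SP5, a list member named after its values were seen, rose against EV 1B9 in edgeR. Its log2 fold change was 5.12 in KO 5H5 (adjusted p 0.0041) and 3.22 in KO 2F4 (adjusted p 0.0253). In KO 2F4 against EV 1B9, LGR6, NOTUM, MMP7, TNFRSF19, SOX4 and FGF18 were called lower.

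Within the list of 43 Wnt ligands, receptors and pathway genes, 6 fell and 37 did not pass. WNT7A, a Wnt ligand, fell by 2.33 on the log2 scale (SE 0.35, adjusted p 0.00564, edgeR), from 277 ± 63.4 to 57.1 ± 16.0 CPM (n = 4 each), and WNT9A fell by 2.59 (SE 0.43, adjusted p 0.0123), from 41.7 ± 18.3 to 7.23 ± 2.46 CPM. SFRP1, a secreted Wnt antagonist, fell by 3.44 (SE 0.64, adjusted p 0.0190), WNT6 by 5.61 (adjusted p 0.0289), the Wnt acyltransferase gene PORCN by 1.53 (SE 0.32, adjusted p 0.0369) and the receptor gene FZD1 by 1.92 (SE 0.41, adjusted p 0.0373), the last 2 named after their values were seen. Adjusted over the list alone, 7 fell and 1 rose, adding FZD8 and DVL2. The list as a whole had a camera adjusted p of 0.098 (0.868 with an estimated correlation), with a median of -0.08 and a mean of -0.64.

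RAS and MAPK genes, the other pathway the title names, gave 1 call in each list. SPRY1, a feedback inhibitor of receptor tyrosine kinase signalling, fell by 5.48 (SE 1.16, adjusted p 0.0373, edgeR) among 23 output genes, from 2.45 ± 1.25 to 0.049 ± 0.098 CPM (n = 4 each). ERBB4, a receptor tyrosine kinase, had no count in the knockout libraries and was at least 35.7-fold lower (adjusted p 0.0266) among 34 pathway components. Adjusted over the list alone the count was again 1 lower gene in each. NRAS was 21.0 ± 15.1 against 16.6 ± 6.47 CPM (-0.40, SE 0.51, adjusted p 0.745). HRAS had 0 or 1 count per library and was not tested. Camera gave the output genes an adjusted p of 0.740 and the components 0.526.

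Cyclic nucleotide genes, closest to the enzyme's function, gave 0 calls over all genes in knockout against control. At an unadjusted p under 0.05 were 5 phosphodiesterases, 3 synthesis and effector genes and 4 responsive genes. Among 11 phosphodiesterases PDE3B, another cAMP phosphodiesterase, had a log2 fold change of -2.57 (SE 0.72, adjusted p 0.108, edgeR; called lower when adjusted over the list alone), and PDE4A was 10.2 ± 2.88 against 20.6 ± 7.88 CPM (0.98, SE 0.40, adjusted p 0.271). Among 15 cAMP and CREB responsive genes, JUNB was lower when adjusted over the list alone (147 ± 22.5 against 61.0 ± 15.4 CPM, log2 fold change -1.31, SE 0.31, adjusted p 0.0619 over all genes), while DUSP1 had 32.1 ± 24.8 against 93.2 ± 46.7 CPM (1.52, SE 0.51, adjusted p 0.173). Camera gave adjusted p of 0.585 for phosphodiesterases, 0.745 for cyclic nucleotide synthesis and effectors and 0.409 for the responsive genes. Single clones against EV 1B9 did give edgeR calls in these lists, in both directions. GUCY1B1 was called lower in KO 5H5 and KO 2F4 (log2 fold changes -3.04 and -2.64) and CREB3L1 higher (6.60 and 7.84). These 2 genes were chosen after their values were seen. CREB3L1 was also called lower in EV 1B9 than in parental (-5.47).

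Among epithelial genes, EPCAM, an adhesion molecule, fell by 3.16 (SE 0.69, adjusted p 0.0410, edgeR), and adjusted over the list alone 5 of 29 fell and CLDN4, a tight junction claudin, rose (15.5 ± 16.3 to 153 ± 98.2 CPM, n = 4 each). ALDH3A1, an aldehyde dehydrogenase in the drug response list, fell by 4.12 (SE 0.66, adjusted p 0.00865), from 97.8 ± 56.2 to 5.69 ± 4.90 CPM. MFAP5, a microfibril gene in the fibroblast marker list, fell by 2.12 (SE 0.46, adjusted p 0.0405). Adjusted over the list alone, the integrin genes ITGA5 and ITGA4 rose (1.43, SE 0.33 and 3.01, SE 0.69), while RHOB (-1.45, SE 0.35), MMP1 (-4.85, SE 1.31) and MMP10 (-5.12, SE 1.43) of the same list fell, MMP1 only through EV 1B9 (135 CPM, with 2.64 in parental, 0.669 in KO 5H5 and 4.39 in KO 2F4), and the stress response gene TRIB3 rose (2.82, SE 0.66), while COL1A2 (-3.37, SE 0.81), ESR1 (-2.62, SE 0.71), HLA-F (-1.41, SE 0.40) and SERPINE2 (-1.68, SE 0.43) fell.

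Camera gave no call for the remaining lists with the preset correlation. Adjusted p was 0.0978 for mesenchymal genes and 0.098 for NF-kB and inflammatory cytokines, and 0.107 for ovarian and Muellerian lineage genes. It was 0.490 for mitosis, p53 targets, hypoxia and glycolysis and mitochondrially encoded genes, 0.577 for the stress response, 0.585 for drug transport, apoptosis regulators and HLA genes, 0.621 for neuronal markers, and 0.636 for ribosomal proteins and endothelial markers. It was 0.740 for DNA replication, interferon-stimulated, epithelial, matrix, cholesterol, respiratory chain and fibroblast genes, 0.894 for histones and 0.909 for integrins and motility. Haematopoietic markers and cancer-testis antigens had too few tested members.

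KO 5H5 was compared with EV 1B9, the control that had also been cloned. Mesenchymal genes were higher in KO 5H5, with 10 of 29 members called higher and 2 lower. The matrix gene FN1 rose from 1.98 to 892 CPM (log2 fold change 8.83, adjusted p 5.21e-05 by edgeR's quasi-likelihood test) and SPARC from 3.10 to 53.6 CPM (4.11, adjusted p 0.00024; n = 2 each), 2 genes chosen after their values were seen. Both genes were also called lower in EV 1B9 than in parental, which had 478 CPM of FN1 and 79.3 CPM of SPARC. Camera gave the mesenchymal list an adjusted p of 8.63e-05, and 0.857 was the lowest of any list with an estimated correlation. KRT14 fell by 13.17 (SE 1.16) and MLLT11 rose by 4.30 (SE 0.51, adjusted p 0.000195). In all 681 of 15551 genes passed, 419 higher and 262 lower, with an even 473 and 473 without a filter. The count was 239 without EV 1B9 1 (121 higher, 118 lower), 317 without EV 1B9 2, 251 without KO 5H5 1, 293 without KO 5H5 2, 1080 without KO 2F4 1 (521 higher, 559 lower) and 1074 without KO 2F4 2.

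KO 2F4 against EV 1B9 gave the most calls of any comparison, 2019 of 15551 genes, with 1069 higher and 950 lower, a balance that turned without a filter (1003 and 1467). KRT5 fell by 14.81 on the log2 scale (SE 1.11, adjusted p 1.36e-05 by edgeR's quasi-likelihood test), from 4223 ± 2520 to 0.123 ± 0.173 CPM (n = 2 each). KRT17, a keratin induced in wounds, fell by 13.84 (SE 1.14) and SPANXB1 rose by 8.19 (SE 0.68, adjusted p 1.36e-05). WNT10A (log2 fold change -6.73, adjusted p 4.11e-05) was lower, a gene chosen after its values were seen. Without EV 1B9 1 the count was 715 (229 higher, 486 lower), without EV 1B9 2 it was 565, without KO 2F4 1 it was 3218 (1414 higher, 1804 lower) and without KO 2F4 2 it was 1038.

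Against the parental line the clones showed fewer calls, more of them lower with all libraries, although without parental 2 the split was 141 higher and 107 lower in KO 5H5 and 143 and 141 in KO 2F4. In KO 5H5, ALDH3A1 fell by 6.06 (SE 0.63, adjusted p 0.000734 by edgeR's quasi-likelihood test) and SFRP1 fell by 3.41 (adjusted p 0.0105), and MLLT11 rose by 3.98 (SE 0.51, adjusted p 0.00154). In all 115 of 15551 genes passed, 18 higher and 97 lower, against 200 (65 higher, 135 lower) with GC and length offsets. That count was 248 without parental 2, 73 without EV 1B9 1, 23 without KO 5H5 1, 19 without KO 5H5 2, 230 without KO 2F4 1 and 231 without KO 2F4 2. In KO 2F4, KRT17 fell by 11.98 (SE 1.08, adjusted p 0.000147), WNT7A fell by 2.23 (SE 0.43, adjusted p 0.0204) and COPZ2 rose by 3.23 (SE 0.44, adjusted p 0.00186). There 208 of 15551 genes passed, 47 higher and 161 lower, against 558 (285 higher, 273 lower) with the offsets and 521 without KO 2F4 1. The beta-catenin target list was lower by camera in both, with adjusted p of 0.0418 in KO 5H5 and 0.00645 in KO 2F4, but not against EV 1B9 (0.178 and 0.139), where the medians were of similar size (-0.71 and -0.57, against -0.62 and -0.59) and fry passed in KO 2F4 (adjusted p 0.00709). SP5 of that list rose against EV 1B9 in both clones, as given above. In KO 5H5 against parental, camera also called the mitosis (0.00797) and mesenchymal lists (0.0418) upward and histones downward (0.0418), but fry called none of them (0.170, 0.364 and 0.737) and edgeR called 0 of their members, with 5, 14 and 2 at an unadjusted p under 0.05. In KO 2F4 against parental, camera called the epithelial list (0.00645, 5 members lower and 1 higher) and the ovarian and Muellerian lineage list (0.00116, 1 member lower) downward. For these 2 comparisons 0.572 and 0.296 were the lowest of any list with an estimated correlation.

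Genes called in both clones were counted with separate controls, since a control shared by both comparisons adds its own chance values. KO 5H5 against parental and KO 2F4 against EV 1B9 shared 13 higher and 60 lower genes, where independent lists would share 1.24 and 5.93. With the controls exchanged, 29 higher and 76 lower genes were shared, against 1.27 and 2.71. MLLT11 and COPZ2 were among the genes higher in all 4 comparisons, and KRT14, DPYSL5, MGAT3 and MATK among those lower. Over all genes the fold changes had a correlation of -0.05 and a covariance of -0.17 with separate controls (-0.01 for simulated lines without an effect), and 0.29 and 0.85 with the controls exchanged; genes are not independent replicates. With EV 1B9 as control of both, 340 higher and 191 lower genes were shared, against 0 in simulations without an effect and 28.8 and 16.0 for independent lists, and the covariance was 2.59 against 0.57 simulated (correlation 0.66 against 0.48), while parental as control of both gave 10 and 52 shared genes, 0.0544 and 1.00 by independence, a covariance of 1.34 against 0.63 and a correlation of 0.47 against 0.50, below the simulated value. The simulated lines had no differences between lines at all, so the simulations cannot separate a knockout effect from changes in EV 1B9 alone. EV 1B9 itself differed from parental in 209 genes by edgeR. The correlation was 0.66 with EV 1B9 shared, against -0.05 and 0.29 with separate controls. Part of the overlap with EV 1B9 as control of both may therefore come from the shared control.

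EV 1B9 against parental measured what differs between control lines without any knockout. KRT81, a hair keratin, had 1 count in EV 1B9 and 6694 in parental, a ratio of 11858 with a 95% counting interval of 2128 to 468439. MARCHF4, a ubiquitin ligase, SYK, a tyrosine kinase, IFT27, a ciliary transport protein, and TENM2, a teneurin, had no count in EV 1B9 and were at least 166-fold, 183-fold, 169-fold and 161-fold lower, with the floor at 3 counts over the line. MMP1, an interstitial collagenase, rose by 5.67 (SE 0.65, adjusted p 0.000327 by edgeR's quasi-likelihood test), from 2.64 ± 0.403 to 135 ± 105 CPM (n = 2 each), and the calcium-binding protein gene CALB1 rose by 3.98 (SE 0.52, adjusted p 0.000904). NID1, TMEM126A and KRT14 rose by between 3.25 and 3.70. In all 209 of 15551 genes passed, 25 higher and 184 lower, against 277 (80 higher, 197 lower) with GC and length offsets, and 6 of the 209 were also among the 192 of knockout against control. The direction depends on single libraries and the filter, with 606 higher and 340 lower without a filter. The count was 620 without parental 2 (377 higher, 243 lower), 60 without EV 1B9 1, 112 without EV 1B9 2, 135 without KO 5H5 1, 826 without KO 2F4 1 (461 higher, 365 lower) and 659 without KO 2F4 2.

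The clones also differed from each other. TIMP3, a metalloprotease inhibitor, had no count in KO 2F4 and was at least 102-fold lower there than in KO 5H5, and ZBTB46, INSYN1 and REV3L, the catalytic subunit of a translesion polymerase, were at least 20.5-fold, 18.2-fold and 36.2-fold lower. KRT17 fell by 9.24 (SE 0.99, adjusted p 0.00118 by edgeR's quasi-likelihood test) from 154 ± 59.4 CPM in KO 5H5 to 0.221 ± 0.312 CPM in KO 2F4 (n = 2 each). PLVAP, an endothelial diaphragm protein, ENPP2, which makes lysophosphatidic acid, and NPNT, an integrin ligand, had no count in KO 5H5 and were at least 140-fold, 25.4-fold and 14.5-fold higher in KO 2F4. RASIP1, a Ras-interacting protein, and HS3ST3A1, a heparan sulfate sulfotransferase, rose by 7.40 (SE 0.87, adjusted p 0.00263) and 6.11 (SE 0.75, adjusted p 0.00334). Camera called 8 of 31 lists between the clones with the preset correlation and 0 with an estimated correlation. In all 61 of 15551 genes passed, 25 higher and 36 lower in KO 2F4, against 149 (73 higher, 76 lower) with GC and length offsets. Of the 61 genes, 4 were among the 192. The count was 101 without parental 1, 34 without EV 1B9 1, 37 without EV 1B9 2, 19 without KO 5H5 1, 10 without KO 5H5 2 and 336 without KO 2F4 1.

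**Figure D3:**
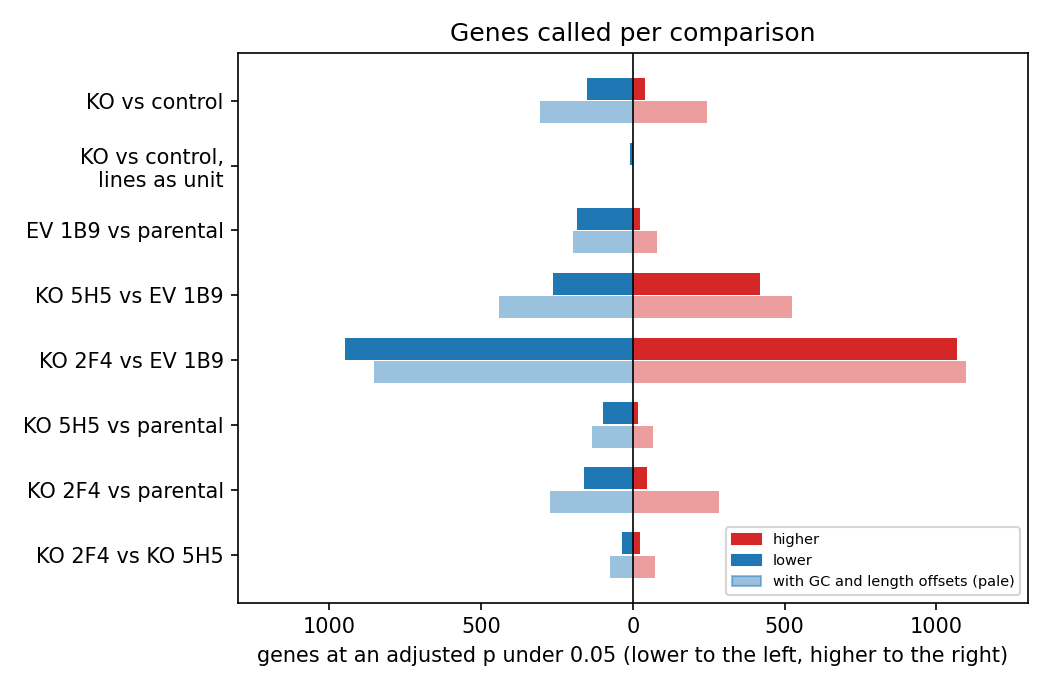
Number of genes at an adjusted p under 0.05 on the horizontal axis, lower to the left and higher to the right, for each comparison on the vertical axis, with full colours for the uncorrected test and pale colours for GC and length offsets. KO 2F4 against EV 1B9 had the longest bars, 1069 higher and 950 lower, and the comparison with lines as the unit the shortest, 1 higher and 10 lower.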

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

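The test with GC and length offsets and both tests of the keratin pattern were chosen after the results were seen. The knockout clones differed from each other in 61 genes by edgeR's quasi-likelihood test of the difference itself, of which 6 fall under the rule for named genes of knockout against control. KRT5 was lower in KO 2F4 than in KO 5H5 by a log2 fold change of -5.18 (SE 0.90, adjusted p 0.0274), with 0.123 against 5.28 CPM. COL1A1, a fibrillar collagen, was lower by -6.32 (SE 1.10, adjusted p 0.0274), with 18.2 against 1450 CPM, and NID2, a basement membrane protein, by -5.70 (SE 1.02, adjusted p 0.0310), with 0.291 against 13.4 CPM. MAL2, a protein of apical transport, was lower by -2.48 (SE 0.47, adjusted p 0.0394), with 2.00 against 11.2 CPM. SPANXB1 was higher by 2.64 (SE 0.52, adjusted p 0.0441), with 185 against 29.7 CPM, and B4GALNT1 by 2.48 (SE 0.44, adjusted p 0.0279), with 142 against 25.5 CPM.

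Single libraries stood apart from the other 3 of their class for 16 of 283 gene and class pairs, where chance alone gives 14.15. Among genes of adhesion and matrix, MFAP2 was 64.9 CPM in KO 2F4 2 against at most 18.5 in the others, COL1A1 was 22.8 CPM in EV 1B9 1 and RHOB 51.0 CPM in KO 5H5 2. Among Wnt and lineage genes, WNT6 was 1.02 CPM and SOX4 34.5 CPM in parental 2, RAI2 was 1.73 CPM in parental 1, and ESR1 was 0.196 CPM in KO 2F4 1. In growth and survival genes, BIRC5 was 130 CPM in EV 1B9 2, MCM2 197 CPM in KO 5H5 2 and BIK 7.13 CPM in parental 1, and the interferon-stimulated gene SP110 was 10.7 CPM in KO 2F4 1. Ribosomal and mitochondrial transcripts also appeared, with RPL22 at 30.5 CPM in parental 2 and 4.29 CPM in KO 2F4 2, RPL26 at 27.9 CPM in EV 1B9 1, and MT-RNR1 at 451 CPM in parental 2 and 708 CPM in KO 5H5 1.

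The 192 genes called between knockout and control libraries are not explained by a GC and length trend between libraries, since 98.9583% passed in the same direction with offsets. Without parental 1 and KO 2F4 2, the libraries with the most reads outside genes, 100% kept their direction with at least 50% of their log2 fold change. The 192 had no overlap between classes, so their direction could not turn in that test, though 180 still passed in edgeR without both libraries. Among the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many genes, and the highest other gave 0 by edgeR, so chance can be excluded for libraries taken as independent units, but 32 of the 34 other splits divide the libraries of a line, which widens their spread, and 2 had more genes at an unadjusted p under 0.05 (up to 2987) than the real one (2041). For differences between lines unrelated to the knockout, 1 of the 3 pairings of the 4 lines gave as many genes (192, highest other 0), and 3 pairings are too few for a share under 0.05. With the line as replicate 11 genes passed, such as KRT14 (-12.96, SE 1.45) and MLLT11 (4.30, SE 0.54), and with GC and length offsets 0 did in edgeR (1471 at an unadjusted p under 0.05, and 263 called by DESeq2 without offsets), where their fold changes held (-13.45, SE 1.86 and 4.26, SE 0.41) but adjusted p for the 11 was 0.143 or more. For the 192 genes, these 11 included, a PDE10A effect and clone-to-clone differences cannot be told apart with 2 lines per side. Loss of PDE10A stays the biological hypothesis the design names.

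The beta-catenin target list was the single list called, and chance cannot be excluded for a count of 1 list, since 34 of the 35 splits called at least 1 list and the highest other split called 8. The list itself was called in 5 of the 35 splits, with a p as small as the real one in 1 of 35. Lines of the same class also differed in lists by camera, on the spread between passages. It called 8 of 31 lists between the knockout clones and 5 of 31 in EV 1B9 against parental. With an estimated correlation 0 lists were called in either.

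For the fall of KRT14, KRT5 and KRT6A, basal epithelial cells mixed into the control cultures would bring their other markers. Yet 9 other markers that are low in the knockout libraries had a median log2 fold change of -0.89 (95% bootstrap interval -2.27 to -0.10), far above -3.5. TRIM29 (-4.14, SE 0.75, adjusted p 0.0178, edgeR) was the single called fall among those 9, which include the basal keratin KRT15 (-0.28, SE 0.73, adjusted p 0.883). JAG2 (-2.18, adjusted p 0.00564) also fell among the 10 other tested markers, whose higher levels in the knockout libraries could hide a small share of such cells, while TP63, the regulator of basal cells, was at 0.0675 CPM in EV 1B9 beside 4223 CPM of KRT5. Clones picked from a mixed parental culture remain open: parental lay below EV 1B9 for 73.7% of the 152 lower genes (112), between the bounds of 75% and 50% set for the test, and lay above EV 1B9 for 35 of the 40 higher genes. Loss of PDE10A is the biological hypothesis, tested with the line as replicate, where KRT14 passed (adjusted p 0.0370) but not with GC and length offsets (0.187), and KRT5 did not pass (0.0998).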

How the results depend on the processing

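Offsets for GC content and length, alone or with the block, the omission of parental 1 with KO 2F4 2, and the list tests with 1 control or 1 clone alone were chosen after the data were seen. RLE size factors moved no count of genes by more than 1.5 times. Over 150 named genes and 21 settings no called direction reversed. The 34 called genes had no overlap between classes, so their direction could not turn where libraries, a clone or a control were left out. These 34 were all kept with RLE, no filter, DESeq2, GC offsets and 1 mean per line. Fewer were kept with limma-voom and the line as random block (11), parental alone (9), without KO 5H5 (18) and without KO 2F4 (18). Small changes were out of reach, since the simulated test of knockout against control recovered 0% of 2-fold changes. The cause of the differences below was not tested except that unfiltered fits test more genes and subsets use fewer libraries.

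For knockout against control (192), the count was 714 without a filter, 780 with DESeq2, 550 with GC offsets, 1108 with a mean per line (515 higher), 34 with limma-voom and the line as random block, 912 with EV 1B9 alone as control (515 higher), 47 with parental alone, 111 without KO 5H5, 83 without KO 2F4, 304 without both parental 1 and KO 2F4 2, and 65 to 228 when 1 library was left out. PDE10A passed in DESeq2 (adjusted p 0.00621), without a filter (0.00184) with a mean per line (0.0165), without KO 2F4 2 (0.0135) and without both parental 1 and KO 2F4 2 (0.00597), and over its alternatives ranged from 0.00184 to 0.357. With lines as the unit (11), it was 279 without a filter, 263 with DESeq2 and 0 with GC offsets in edgeR (1471 genes at an unadjusted p under 0.05).

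Without a filter, EV 1B9 against parental gave 946 genes (606 higher), KO 5H5 against parental 259, KO 2F4 against parental 465 and KO 2F4 against KO 5H5 272. DESeq2 gave 1349 for EV 1B9 against parental, 1375 and 3428 for KO 5H5 and KO 2F4 against EV 1B9, 363 and 727 for them against parental, and 348 for KO 2F4 against KO 5H5. GC offsets gave 200 for KO 5H5 and 558 for KO 2F4 against parental, and 149 for KO 2F4 against KO 5H5. Leaving out 1 library gave 60 to 826 genes for EV 1B9 against parental, 239 to 1080 and 565 to 3218 for KO 5H5 and KO 2F4 against EV 1B9, 19 to 248 and 139 to 521 against parental, and 10 to 336 between the clones. With EV 1B9 as control of both clones, 531 genes were shared in place of 73.

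The number of lists called (1) was 0 with an estimated correlation (1 at an unadjusted p under 0.05), 4 without a filter, 2 with EV 1B9 alone, 3 without KO 5H5, 4 without KO 2F4, 4 without both parental 1 and KO 2F4 2, and 0 to 4 when 1 library was left out. The adjusted p of the beta-catenin targets (0.0211) was 0.398 with an estimated correlation, 0.167 with EV 1B9 alone, and 0.0052 to 0.0682 when 1 library was left out, and stayed under 0.05 in the other settings.

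As a replicate block, the title suffix gave 124 genes for knockout against control and 35 for KO 2F4 against KO 5H5, and with GC offsets and the block 423 for KO 2F4 against parental and 92 for KO 2F4 against KO 5H5. The suffix does not pair the samples, since differences between the 2 libraries of a line correlated between lines at -0.23 to 0.25, and other counts moved by less than 1.5 times under the block.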

Other observations

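The test of neighbouring genes was planned before its result was seen, while the genes and regions named here were chosen after their values were seen. Inflammatory genes of the NF-kB list separated the lines in a way not described above. In EV 1B9 against parental 4 of 24 members fell, C3, a complement component (35.0 to 0.296 CPM, log2 fold change -6.95, adjusted p 0.000222 by edgeR's quasi-likelihood test), CXCL1, IL32 and LCN2, and the list was lower by camera (adjusted p 0.00118, and 0.916 with an estimated correlation). In KO 2F4 against EV 1B9 10 of 24 rose, among them C3 (0.296 to 74.8 CPM, 8.05, adjusted p 3.54e-05), the chemokine gene CXCL1 (2.79 to 45.1 CPM, 4.01, adjusted p 0.00133) and NFKB2 (2.64, adjusted p 0.00204), and camera gave 7.65e-05 (0.437 with an estimated correlation). KO 5H5 also had IL6, IL32, NFKB2 and C3 called higher than EV 1B9 in edgeR, with C3 at 10.7 CPM (log2 fold change 5.23, adjusted p 0.00063). Between the clones the list was higher in KO 2F4 by camera (adjusted p 0.000158) but not with an estimated correlation, with 0 members called in edgeR and 2 higher when adjusted over the list alone. EV 1B9 thus had the lowest level of C3 and CXCL1 among the 4 lines, while the mean CPM of KO 2F4 lay above both controls, without a call against parental for either gene. Short lists of other cell types moved with the inflammatory list by camera, since endothelial markers were lower in EV 1B9 than in parental (adjusted p 0.0359) and higher in KO 2F4 than in EV 1B9 (0.0193), as were haematopoietic markers (0.0377), but these calls were lost with an estimated correlation (0.916, 0.437 and 0.437).

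Some mesenchymal genes were also low in EV 1B9. FN1 was 478 CPM in parental, 1.98 in EV 1B9, 892 in KO 5H5 and 789 in KO 2F4, so that it fell in EV 1B9 against parental (adjusted p 0.000222, edgeR). CNN1, a smooth muscle calponin, was 4.08 CPM in parental, 0 in EV 1B9, 24.2 in KO 5H5 and 0.109 in KO 2F4, and fell between KO 5H5 and KO 2F4 (adjusted p 0.0133). The cholesterol and fatty acid list was called upward in EV 1B9 against parental by camera (adjusted p 0.0171, and 0.916 with an estimated correlation), but 0 of 34 members were called in edgeR, with 12 at an unadjusted p under 0.05.

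Genes that lie next to each other shifted together between lines, and copy number differences between the lines are a candidate explanation. With GC and length adjustment, 169 windows of 50 neighbouring genes, summed over 6 comparisons of 292 windows each, had a median shift over 0.5 on the log2 scale, against at most 12 in 100 shuffles of the gene order, a result in line with copy number differences, although no DNA was measured. The 5 windows spanning chromosome 13 from 18697003 to 113099739 were lower against EV 1B9 in both clones, with medians of -0.86 to -0.61 in KO 5H5 and -1.19 to -0.88 in KO 2F4, and the window from 3126916 to 11263557 on chromosome 3 was higher by 0.90 and 1.05. Part of this shared shift lies in the control, since EV 1B9 against parental shifted by -0.52 in the chromosome 3 window, by 0.66 and 0.51 in 2 windows of chromosome 13 and by 0.63 in the keratin window described next. Against parental, the chromosome 3 window was not over 0.5 in either clone, and 2 windows of chromosome 13 stayed lower in KO 5H5 (-0.65 and -0.56) and 4 in KO 2F4 (-0.79 to -0.59). The window from 39566915 to 42021376 on chromosome 17, which holds KRT14 and KRT17, was lower by medians of -0.82 and -0.98, a shift far smaller than the log2 fold changes of KRT14, -13.17 in KO 5H5 and -15.01 in KO 2F4. EV 1B9 against parental had 12 such windows (at most 3 in shuffles) and KO 2F4 against KO 5H5 had 16 (at most 2). Some other windows were higher in both clones against both controls, so their shift does not come from EV 1B9 alone. From 497258 to 6059230 on chromosome 7, KO 5H5 and KO 2F4 shifted by 0.62 and 0.82 against EV 1B9. Against parental they shifted there by 0.67 and 1.01. From 4788959 to 7571969 on chromosome 17 the shifts were 0.82 and 0.63 against EV 1B9, and 0.90 and 0.65 against parental.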
